A study of Drosophila melanogaster with 4 samples.

How the data were processed

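Small RNAs of adult fly heads and thoraces were sequenced from 4 libraries, 1 for each genotype: heterozygotes over the CyO balancer chromosome and homozygotes of a loqs knockout, and heterozygotes and homozygotes of an r2d2 mutant. Per the labels' protocols, total RNA was run on a gel, RNAs of 19 to 25 nt were cut out, adapters were ligated to both ends, and barcodes were added by PCR. The deposited files hold FASTQ reads, not counts per gene: the 3' linker had been removed and the reads had been separated by library before deposit, as the reads themselves show. The trimming tool and the genome build are not given in the sources used here. Bowtie is named, without a version, per the submitters' processing notes. A note deposited with the series states that maps to a transposon collection and to the CG4068 hairpin locus belonged to the samples. Those maps were not used here.

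Files of both loqs genotypes and of the r2d2 heterozygote held reads of 19 to 25 nt, and the file of the r2d2 homozygote held reads of 21 nt only. The r2d2 comparison therefore used 21 nt reads throughout, and alternatives with other lengths were run for loqs alone. Read sequences were converted to upper case and tallied with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.

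No reference file of genome, transposon or miRNA sequence was used here. miRNA names came from a list of 129 mature arm sequences written from memory of textbook and database sequences, so each name rests on that list. A read was given an arm when positions 3 to 19 of the listed sequence began within 2 nt of their place in the read. Of the 78 arms with at least 50 reads, the most frequent read began as listed for 71. Paralogues that share positions 3 to 19 were counted as 1 arm. Coordinates came from the Ensembl annotation of genome build BDGP6. The hairpin siRNA comparison, planned over several loci, was limited to esi-2.1 of the CG4068 hairpin, and the structural RNA comparison to 2S rRNA. Transposon, cis-NAT, piRNA and targeted-gene reads were not analysed here, because they need sequences that were not used.

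Shares of reads carry exact Clopper-Pearson 95% intervals and ratios of shares carry exact conditional binomial 95% intervals. With 1 library per genotype no test between genotypes was possible and no p-value is given. The reads carry no molecular identifiers, so intervals and limits cover counting error only, and every difference lies between libraries and has no replicate check. A count of 0 was given the limit of 3 reads. For arms, CPM were taken over reads with a listed arm, with a pseudocount of 0.5 reads. Arms with at least 50 reads over both libraries and at least 10 expected in the shallower one entered the comparison, and a 2-fold difference was the size rule. The arms named are the 10 highest and the 10 lowest of each comparison and the members of fixed lists, a rule set before the data were examined. A list's median was placed among 10000 random lists of the same size, matched on expression in 5 bins. Scaling by TMM factors and by median-of-ratios factors was written in Python.

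Small interfering RNAs were sought without a reference, a step added after the data were examined. Pairs of 21 nt reads whose first 19 nt were reverse complements, as in duplexes with overhangs of 2 nt, were taken with at least 2 reads per strand, after miRNA and 2S rRNA reads were set aside. Reads sharing 15 nt were joined into clusters. A cluster with at least 50 reads in both heterozygous libraries together, of which at least 50% were 21 nt long, was called siRNA-type. The catalogue of pairs was first drawn from the heterozygous libraries alone. That leaves out sequences seen in a homozygous library only and lowers its ratio by construction, so pairs from all 4 libraries were used for the values reported, and the first version is among the alternatives. This removes the bias in part only. The rules on reads and length still use the heterozygous libraries, so clusters with few reads there stay left out under every catalogue. Clusters are named by number, and their sequences and genomic origin were not determined.

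The steps were tested on simulated data. All 1935 simulated reads of the 129 listed arms with a 5' end within 2 nt of the listed one were given their own arm, and 0 of 20000 random reads were given any. The simulated arm reads were built from the list with the shifts that the rule allows. Their match was thus fixed by construction, and the run shows only that listed arms were not mistaken for each other. In the loqs simulation, run on 93 arms, 98.5% of arms changed 3-fold and 100% of those changed 4-fold passed the 2-fold rule, and in the r2d2 simulation, run on 85 arms, 100% passed at both sizes. All 20 simulated diced RNAs were found as siRNA-type clusters and 0 of 20 simulated breakdown products were, in the run of each comparison. Breakdown reads were spread evenly over read lengths, so the rule of at least 50% of 21 nt reads excluded them by construction. Both runs held 10000 homozygous reads, against 120 in the 75 clusters of the loqs homozygote. They therefore do not test the step at that depth, where 3 clusters had at least 10 expected reads. These simulations hold counting noise only.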

Results

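Small RNA libraries were compared between homozygous mutants and heterozygous controls for loqs, which encodes double-stranded RNA binding partners of Dicer enzymes, and for r2d2, which encodes a partner of Dicer-2. Both genes lie on chromosome 2L in genome build BDGP6, loqs from 13382652 to 13385671 and r2d2 from 7800147 to 7802098. Each genotype had 1 library. The loqs heterozygote gave 2405256 reads and the loqs homozygote 47532, of which 538177 and 9829 were 21 nt long. The r2d2 heterozygote gave 1771480 reads, 510460 of them 21 nt long, and the r2d2 homozygote gave 1105195, all of 21 nt. The loqs homozygote was thus the shallowest library, and a count of 0 in it allowed up to 305.2 ppm of 21 nt reads, against 2.71 ppm in the r2d2 homozygote.

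The controls set a yardstick for differences between libraries. Between the heterozygous libraries, 44 of 76 miRNA arms differed by at least 2-fold over all lengths, and 28 of 65 did among 21 nt reads. In the loqs comparison 26 of 54 arms did, and in the r2d2 comparison 20 of 68. Neither share exceeded that between the controls measured over the same read lengths. Of the 20 arms with the largest changes, 10 in each direction, 15 in the loqs comparison and 11 in the r2d2 comparison changed by more than the same arm differed between the controls, 10 and 8 of them with counting intervals apart. Sizes were compared without regard to direction, and each comparison shares its heterozygous library with the difference between the controls. The 20 arms were picked for a large change between genotypes, so many would exceed an unpicked difference through library spread alone. These counts therefore show no excess over the controls. Over all arms the standard deviation of log2 ratios was 2.07 between the controls and 1.67 for loqs over all lengths. Among 21 nt reads it was 1.79 between the controls and 1.01 for r2d2. The intervals overlapped for miR-263b-5p, miR-87-3p, miR-987-5p, miR-14-5p and miR-276b-3p in loqs and for miR-87-3p, miR-932-5p and miR-252-5p in r2d2. Of miR-989-3p, at 0 reads in the loqs homozygote, only a bound is known, and it lies below the difference between the controls. Those that did not exceed it were miR-133-3p, miR-8-5p, miR-275-3p and miR-79-3p for loqs, and bantam-3p, miR-184-3p, miR-987-5p, miR-2a-3p, miR-995-3p, miR-277-5p, miR-9b-5p, miR-79-3p and miR-970-3p for r2d2.

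In the loqs homozygote, miR-263b, miR-263a and let-7 had a larger share of miRNA reads and miR-314 and miR-989 a smaller one, both over all lengths of 19 to 25 nt and among 21 nt reads. Of these, miR-263a, let-7 and miR-314 changed over all lengths by more than the controls differed, intervals included. The r2d2 heterozygote differed from the loqs heterozygote in the same directions, at log2 ratios of 1.20, 0.66 and -0.59, against changes of 1.88, 1.51 and -3.23. Among 21 nt reads these control differences were 0.71, -0.65 and -2.14, against changes of 1.81, 1.24 and -3.76. For let-7 the direction was then opposite. An unusual loqs heterozygote would move both values where they share a direction. With 1 library per genotype, none of these changes can be assigned to the mutant. Over all lengths, of 54 arms, 13 were at least 2-fold higher and 13 at least 2-fold lower than in the heterozygote. The highest was miR-263b-5p, encoded in an intron of meru on chromosome 3L from 15843406 to 15843495, at 6.02-fold (interval 5.52 to 6.57), or 2.59 on the log2 scale against 2.43 between the controls. It was followed by miR-87-3p at 3.96-fold (2.75 to 5.55), miR-263a-5p at 3.67-fold (3.46 to 3.90) and let-7-5p, a regulator of developmental timing, at 2.84-fold (2.75 to 2.93). The lowest was miR-989-3p, encoded on chromosome 2R from 14145351 to 14145524. It had 4405 reads in the heterozygote and 0 in the homozygote, where 129.3 were expected. With the count of 0 set to its limit of 3 reads that is 43.1-fold lower, and the exact interval of the ratio reached 0.0285. The ratio of miR-314-3p was 0.106 (0.0763 to 0.142), that of miR-14-5p 0.101 (0.0273 to 0.258), or 0.225 with a pseudocount of 5 reads, and that of miR-31a-5p 0.178 (0.131 to 0.236), or 0.484 (0.270 to 0.802) among 21 nt reads. With 21 nt reads only, 4 arms were higher and 15 lower.

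By fixed list and over all lengths, both muscle arms were higher, miR-1-3p at 2.31-fold (2.24 to 2.39) and miR-133-3p at 2.54-fold (1.88 to 3.37), and their median log2 ratio of 1.28 lay at percentile 96.9 of random lists. Among 21 nt reads, however, miR-1-3p stood at 0.980-fold (0.885 to 1.08) and miR-133-3p had too few reads, and between the controls miR-133-3p differed by 2.61 on the log2 scale. Of 7 nervous system arms, 2 were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.69 at percentile 97.8, but among 21 nt reads 0 of 3 were higher and 1 lower, with a median of -0.449 at percentile 40.0. Over all lengths miR-7-5p stood at 2.15-fold (1.97 to 2.34) and miR-124-3p at 0.572-fold (0.436 to 0.738). Of 15 arms of the abundant Ago1-bound list, 4 were higher and 3 lower, at percentile 20.4, which became 85.6 for 12 arms among 21 nt reads. The Ago2-sorted miR-277-3p stood at 2.76-fold (2.45 to 3.10), with too few reads at 21 nt. Of 3 arms listed for Loqs-dependent or trimmed ends, 1 was higher and 1 lower, at percentile 34.0. Reads of 1 of them, miR-34-5p, had a ratio of 0.343 (0.319 to 0.370), or 0.203 (0.179 to 0.229) among 21 nt reads, and 21.4% of them were 22 nt long in the homozygote, 9.23% in the heterozygote and 1.10% in the r2d2 heterozygote, a larger ratio between the controls than between the loqs libraries. Of miR-87-3p reads, 34.2% (19.6 to 51.4), or 13 of 38, were 24 nt long in the loqs homozygote, against 0 of 327 in the loqs and 0 of 45 in the r2d2 heterozygote. Of miR-307a-3p reads, 55.9% (37.9 to 72.8) were 22 nt long in the homozygote, 52.4% in the heterozygote and 67.7% in the r2d2 heterozygote. The gut and fat body list had 1 arm that passed, miR-275-3p, at 0.350-fold (0.294 to 0.412), but at 0.648-fold (0.435 to 0.929) among 21 nt reads, short of 2-fold. No arm of the mirtron or testis lists passed the read filter in either comparison, and 1 ovary arm, miR-989-3p, did in the loqs comparison alone.

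Listed miRNAs made up 66.1% (65.2 to 67.1) of 21 nt reads in the loqs homozygote and 35.8% (35.7 to 36.0) in the heterozygote, a ratio of 1.85 (1.80 to 1.89). The matching rule left out 64373 of 75402 bantam-3p reads of 21 nt in the heterozygote and 314 of 727 in the homozygote, for another 5' end. With the 5' end left free the ratio was smaller, as given below, and lay outside that interval. The miRNA ratio was 1.48 over all lengths. In the r2d2 heterozygote the miRNA share was 50.7% at 21 nt and 31.3% over all lengths. The loqs heterozygote stood at 43.1% over all lengths. 2S rRNA, a structural RNA read as breakdown, was also higher, at 2.36-fold (1.96 to 2.81) among 21 nt reads and 3.61-fold (3.35 to 3.89) over all lengths. Over all lengths the controls differed by more, at 4451.5 ppm in the loqs and 20565 in the r2d2 heterozygote. At 21 nt they stood at 5526 and 5162 ppm. Minor miRNA arms took a median of 2.66% of a hairpin's reads in the homozygote and 2.25% in the heterozygote over 10 hairpins, while the median of the differences per hairpin was -0.154 percentage points, of the opposite sign.

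The hairpin siRNA esi-2.1 is annotated on chromosome X from 4921677 to 4928133, overlapping an exon of CG44774. The loqs homozygote had 0 reads of it at 21 nt and the heterozygote 28, of 100 over 19 to 25 nt. At the heterozygous level only 0.511 reads were expected in the homozygote, and 1.98 over all lengths. A loss of esi-2.1 was therefore not detectable at this depth, and the interval of the ratio reached 7.71.

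Among 21 nt reads, the only length in the file of the r2d2 homozygote, the muscle miRNA miR-1-3p had a smaller share of miRNA reads in the homozygote, and miR-274 a larger one. A shift of an arm's reads between lengths would also move such a share, and 89.8% of miR-1-3p reads were 21 nt long in the r2d2 heterozygote against 21.8% in the loqs heterozygote. Of 68 arms, 14 were at least 2-fold higher and 6 at least 2-fold lower, or 11 and 8 with TMM scaling. These are shares of miRNA reads, so the fall of miR-1-3p from 280313 to 41386 CPM by itself raises the share of every other arm. The ratio of miR-1-3p was 0.148 (0.146 to 0.150), and that of miR-995-3p was 0.301 (0.262 to 0.345). Higher arms were miR-87-3p at 4.03-fold (2.54 to 6.76), but 2.09-fold with the listed 5' end only, miR-274-5p at 3.86-fold (3.21 to 4.68), miR-252-5p at 3.29-fold (2.50 to 4.40) and miR-184-3p at 3.26-fold (3.13 to 3.40), which differed by 2.50 on the log2 scale between the controls. The growth regulator bantam-3p stood at 4.68-fold (4.51 to 4.87), but at 1.80-fold (1.75 to 1.84) when reads with a changed 5' end were included. miR-2a-3p, at a log2 ratio of -2.27, and miR-987-5p, at 1.35, each changed direction with the rule for the 5' end.

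Of the fixed lists in the r2d2 comparison, the 18 abundant Ago1-bound arms had a median log2 ratio of 0.58, at percentile 95.1, with 4 higher and 1 lower. Both muscle arms had a median of -1.42, at percentile 2.12, with miR-133-3p at 0.951-fold (0.796 to 1.14). The 9 nervous system arms lay at percentile 52.0 and the 4 gut and fat body arms at percentile 56.0. Of the arms of miR-277, the 5' arm stood at 0.356-fold (0.222 to 0.567), or 0.505 with the listed 5' end only, and the 3' arm at 0.645-fold (0.571 to 0.731), at percentile 9.73. The 3 arms listed for ends lay at percentile 46.6.

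Listed miRNAs made up 55.2% (55.1 to 55.3) of reads in the r2d2 homozygote and 50.7% (50.6 to 50.9) of 21 nt reads in the heterozygote, a ratio of 1.09 (1.08 to 1.09), which was 0.996 when only reads with the listed 5' end were counted. The controls differed by more, since the loqs heterozygote stood at 35.8%. The ratio of 2S rRNA was 0.786 (0.749 to 0.825). Over 12 hairpins the median difference in the share of the minor arm was -0.0394 percentage points. esi-2.1 had 103 reads in the homozygote and 48 in the heterozygote, a ratio of 0.991 (0.697 to 1.43). The ratio of miRNA ratios, loqs over r2d2, was 1.70 (1.66 to 1.74), with no replicate spread to test it. It was smaller with the 5' end left free and larger with the listed 5' end only.

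**Figure D1:**
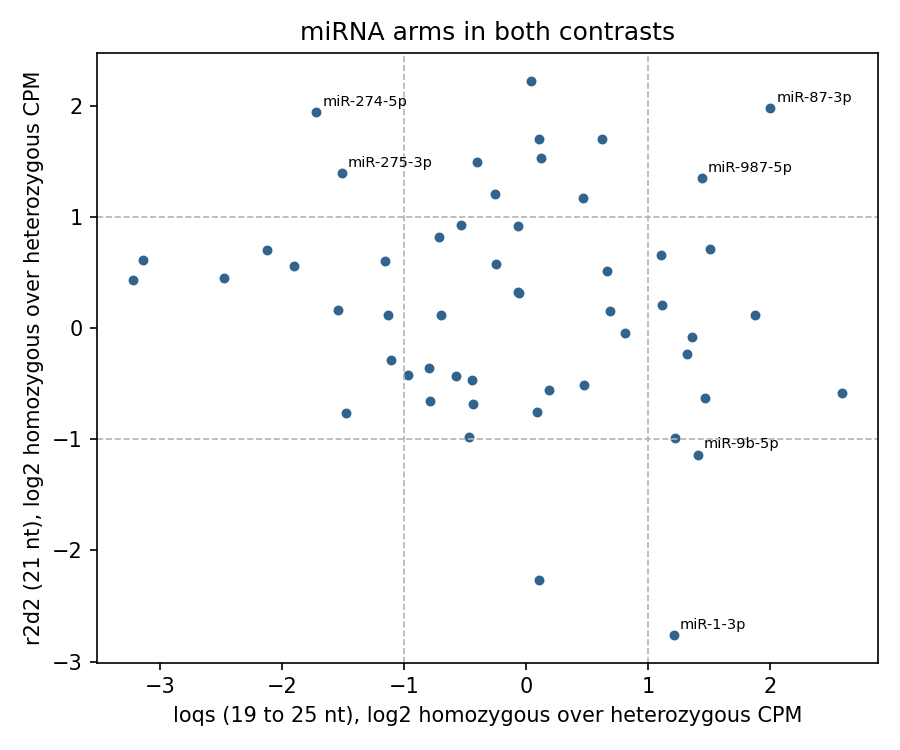
The log2 ratio of CPM, homozygous over heterozygous, of the 53 miRNA arms that passed the read filter in both comparisons, loqs over 19 to 25 nt on the horizontal and r2d2 at 21 nt on the vertical axis, with dashed lines at 2-fold. Of these, 4 arms passed 2-fold in opposite directions and 2 in the same direction, but with 21 nt reads on both sides 0 of 36 arms did so in opposite directions and 1 in the same, and each axis rests on 1 library per genotype.

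In the r2d2 homozygote the siRNA-type clusters fell into 2 sets, those near 0 and those still present. Of 75 clusters, 70 had at least 10 reads expected in the homozygote. Of these, 37 were at least 10-fold lower, with 9 reads in all where 24728 were expected, and the other 33 had ratios from 0.119 to 4.71 with a median of 0.616, 17 of them with intervals below 1 and 5 above 1. Summed over these 33 the ratio was 0.761, but clusters 2, 3 and 6 held 10327 of their 15167 homozygous reads, and without these 3 it was 0.631. Cluster 1 alone went from 6621 reads to 1. The same 37 clusters had 7135 reads in the loqs heterozygote and 107 in the loqs homozygote, a ratio of 0.821 (0.672 to 0.994), or 0.477 (0.349 to 0.637) without cluster 1, which held 61 of the 107 reads. Over all 75 clusters the ratio was 0.342 (0.335 to 0.349) for r2d2 and 0.804 (0.666 to 0.963) for loqs. The loqs value turned to 1.57 (1.30 to 1.88) over reads of neither miRNA nor 2S rRNA, and its interval reached 1 with 3 reads per strand, at 0.913 (0.751 to 1.10), with the catalogue of either r2d2 library, and without the 37 clusters. It was lower at 0.512 (0.389 to 0.661) without cluster 1 and at 0.436 (0.361 to 0.522) per miRNA read, so its direction depends on the denominator and its size on the clusters counted. The r2d2 value ranged from 0.00447 to 0.819 with the library from which the catalogue of duplexes was drawn. The split into 37 and 33 clusters was made from the ratios themselves, after they were seen. Every cluster also had to reach 50 reads in the heterozygous libraries, which can lower these ratios by construction.

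**Figure D2:**
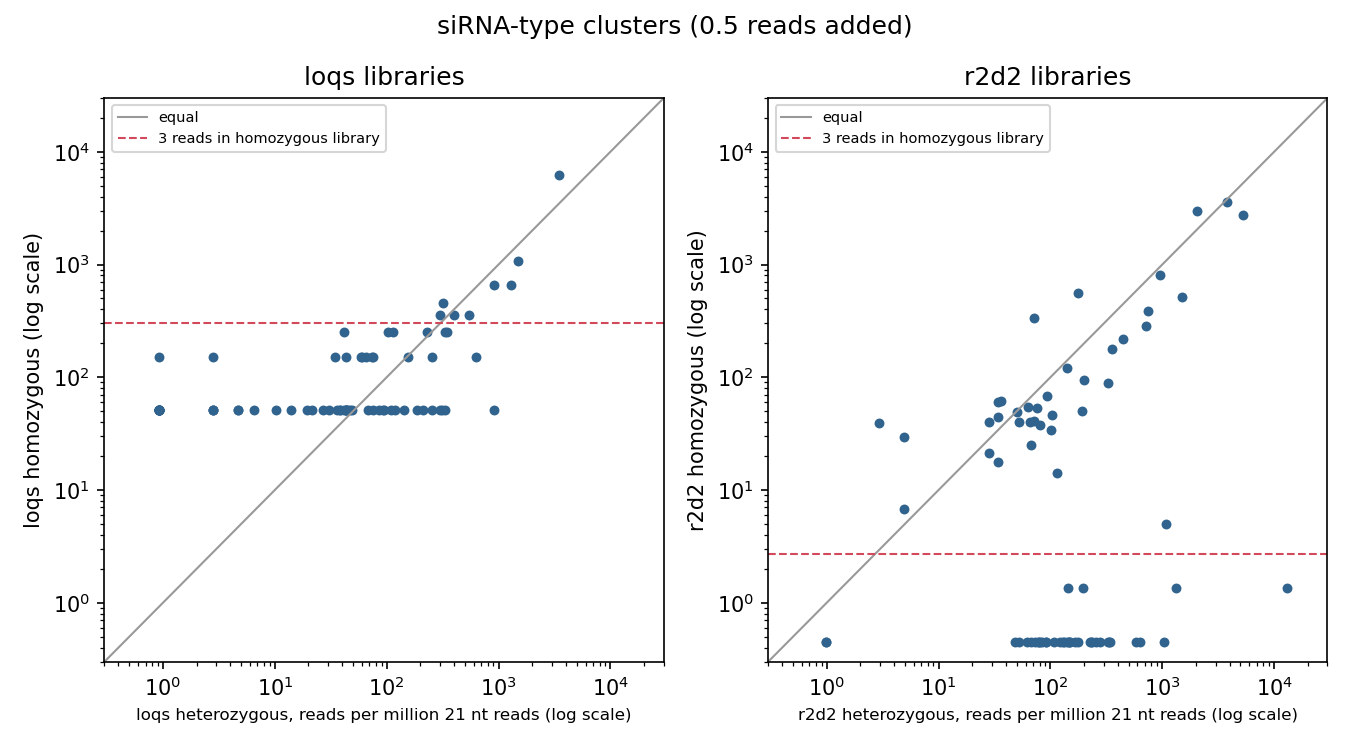
Reads, in ppm of 21 nt reads, of each of the 75 siRNA-type clusters, heterozygous library on the horizontal and homozygous on the vertical axis, both log scales with 0.5 reads added. Points under the dashed line had fewer than 3 reads in the homozygous library, and in the r2d2 panel a set of clusters lies under it at heterozygous levels up to that of cluster 1.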

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

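All tests in this part were chosen after the results were seen, except that of the most frequent miR-989 sequence. In 4 miRNA arms the loqs comparison, over 19 to 25 nt, and the r2d2 comparison, at 21 nt, went in opposite directions by at least 2-fold each. The difference of log2 ratios, loqs minus r2d2, was 3.97 for miR-1-3p, -3.67 for miR-274-5p, -2.91 for miR-275-3p and 2.55 for miR-9b-5p. With 21 nt reads in both, 0 of 36 arms did so: the difference was 2.73 for miR-1-3p and -2.001 for miR-275-3p, whose loqs ratios were then under 2-fold, and miR-274-5p and miR-9b-5p had too few loqs reads. None of these differences was tested, since each genotype had 1 library. Reads of the lac operator, a sequence of cloning vectors, were above the limit of a count of 0 in 3 libraries. They stood at 163.5 ppm of 21 nt reads in the loqs heterozygote, 3877 in the r2d2 heterozygote and 464.2 in the r2d2 homozygote. The r2d2 ratio was 0.120 (0.108 to 0.132). Their source was not determined, and they serve below for a bound on barcode cross-talk.

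The first pattern weighed is the set of 37 siRNA clusters near 0 in the r2d2 homozygote. A fall of every 21 nt siRNA to a ratio of 0.5 or less without R2D2 is argued against by 13 clusters whose ratio intervals lay wholly above 0.5, or 6 with pairs from both heterozygous libraries alone and 1 of 11 with pairs from the loqs heterozygote, and a smaller loss is not excluded. Low depth is argued against by the 1105195 reads of 21 nt in the r2d2 homozygote, against 510460 in its heterozygote. The 24728 reads expected add no test, since only clusters with at least 10 expected reads were taken. The CyO balancer as the source of all 37 clusters is argued against by the loqs homozygote, which lacks that chromosome. It held 0.573% (0.470 to 0.692) of these clusters' reads, or 0.454% (0.333 to 0.605) without cluster 1. Both lie above a bound for barcode cross-talk of 0.208%, taken from lac operator and miR-989 reads of all lengths. The cluster reads were 21 nt long. At that length the lac operator had 2 reads in the loqs homozygote and 1979 in the r2d2 heterozygote. No bound was computed from so few, so whether the value without cluster 1 clears one at like length stays open. Only 18 of the 37 clusters had reads in the loqs homozygote, so a CyO source stays open for the others. A virus or another RNA that the flies of the r2d2 homozygous library did not carry could account for the set, as could an effect of R2D2 on these RNAs alone, and nothing here separates them, with 1 library per genotype.

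The second pattern is miR-989 in the loqs heterozygote. Ovary tissue carried over stays open: the other ovary miRNAs had a ratio to the r2d2 heterozygote of 0.816 (0.609 to 1.10), but members went both ways, from miR-994-5p at 0.104 (0.0391 to 0.237) to miR-92a-3p at 6.96 (1.74 to 60.5), and without miR-994-5p the ratio was 1.43 (0.993 to 2.09). The share of the most frequent of its 38 sequences, 70.9%, lay between the median of 66.5% and the highest value of 93.0% over 43 other arms and decided nothing. As the source of the difference from the r2d2 heterozygote, amplification of 1 molecule is argued against by 245 reads whose first 19 nt differed from that sequence by more than 1 base, of which that library had 0, with a lower bound of the ratio of 35.3. For the difference from the loqs homozygote it stays open, since 7.19 such reads were expected there, under the bound of 10, and the loqs genotype, not tested, may also bear on it.

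The third pattern is a changed 5' end of bantam reads, which began with CTG in 79.6% of 21 nt bantam reads of the loqs heterozygote, 40.3% of those of its homozygote, 58.7% in the r2d2 heterozygote and 4.01% in its homozygote. With the 5' end left free the loqs ratio of bantam was 0.517 (0.490 to 0.544), against 1.03 (0.967 to 1.09), an interval that spans 1, so whether the matching rule turns its direction stays open. A change common to all miRNAs is argued against by the 0.00109% of other arms' reads that began so. A sequence-specific ligation or priming event is a candidate explanation that was not tested.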

How the results depend on the processing

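No paired analysis was possible because each genotype had 1 library. Alternatives on the 5' end, on siRNA clusters, on lists at 21 nt and on like lengths in both comparisons were chosen after seeing the data. Of 66 alternative values of the main results, 41 stayed within the main value's counting interval or, for counts of arms, within 1.5-fold, and of 244 log2 ratios of named arms 192 stayed within the interval. Transposon, cis-NAT and antisense alternatives were not run, nor were other lengths for r2d2. Causes were not tested unless given. The loqs homozygote's depth limits esi-2.1 and most clusters.

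The loqs miRNA ratio was 1.48 over all lengths and 1.45 with the 5' end left free. That of r2d2 was 1.07 with it free and reversed to 0.996 with the listed end only, and the ratio between comparisons was 1.35 and 1.90 under these rules. The loqs 2S rRNA ratio was 3.61 over all lengths, where the controls differed by more. Without the read filter, which admits arms of few reads, 33 loqs arms were higher, and 23 r2d2 arms were higher and 17 lower. With 21 nt only, 4 loqs arms were higher, and the loqs list medians changed sign for abundant Ago1-bound arms, at percentile 85.6, and nervous system arms, at percentile 40.0. TMM scaling gave 11 higher and 8 lower for r2d2, 57.9% higher against 70%. It lowered every r2d2 log2 ratio by 0.19 and median-of-ratios scaling did so by 0.14. Neither turned a named arm's direction, but both took miR-8-5p and miR-281-3p past 2-fold lower. In r2d2, miR-987-5p reversed to -1.001 with the listed end only and miR-2a-3p to 0.23 with it free.

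The r2d2 duplex siRNA ratio was 0.240 with a catalogue from both heterozygotes, 0.00447 from the loqs heterozygote, 0.244 from the r2d2 heterozygote and 0.819 from the r2d2 homozygote. All these catalogues kept the rules on heterozygous reads. The r2d2 ratio was 0.334 with 1 read and 0.354 with 3 reads per strand, 0.314 per miRNA read, 0.375 per read of neither miRNA nor 2S rRNA, 0.503 without cluster 1 and 0.765 without the clusters 10-fold lower, which were picked by this ratio. The loqs ratio was 0.573 with a catalogue from the loqs heterozygote, 0.436 per miRNA read and 0.512 without cluster 1, and it reversed to 1.57 per read of neither class.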

Other observations

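The libraries differed in length profile. Reads of 22 nt were the most frequent in both loqs libraries, at 28.2% in the heterozygote and 29.7% in the homozygote, and reads of 21 nt in the r2d2 heterozygote, at 28.8%. Reads of 19 nt made up 8.57% of the loqs homozygote and 17.5% of the r2d2 heterozygote. Among ovary miRNAs other than miR-989, the r2d2 heterozygote had 78 reads, or 140.6 CPM over miRNA reads, the loqs heterozygote 119, or 114.8 CPM, and the loqs homozygote 0, with an upper bound of 121.2 CPM that does not separate it from the loqs heterozygote. The r2d2 homozygote had 3, or 4.92 CPM (1.01 to 14.4), at 21 nt only, and at that length miR-318-3p went from 13 reads to 3, a ratio of 0.0980 (0.0179 to 0.357), and miR-994-5p from 11 to 0.

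A hypothesis was set out before its result was seen: that R2D2 sets which strand of a duplex is kept. The share of duplex reads from the strand with more A or T in its first 4 nt was 89.6% in the r2d2 heterozygote and 73.5% in the homozygote over 14 clusters, a difference of -16.2 percentage points with a bootstrap interval over clusters of -31.6 to -3.61. That met the prediction as written. It fell in 8 of the 14 clusters, and leaving out each in turn gave -19.3 to -10.7. A stricter condition, added after the pooled value was seen, weighted clusters equally and gave -9.41 (-23.3 to 3.37), which includes 0. The result may reflect a few abundant clusters, and it stays open.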
